A study of Mus musculus with 16 samples.

How the data were processed

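Total liver RNA of female C57BL/6J mice had been measured on 1-colour Illumina MouseRef-8 bead arrays, 1 array per sample, with no pooling stated. The 16 arrays held 4 groups of 4: regular chow and high-fat diet (HFD) on the first chip of 8, and HFD and HFD with intraperitoneal nicotinamide mononucleotide (NMN) for 7 days on the second. Groups were taken from the sample titles and the design text. The software that read the arrays and the hours at which livers were collected are not given in the sources used here.

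The deposited signal table holds an intensity for each of 25697 probes on a linear scale. The authors scaled it, since every array has the same mean of 202 over all probes; no background had been subtracted. Beside each intensity, the deposited table gives a detection p-value per probe and array, per the file headers. A second deposited table of 18118 values per array holds a z score, which the authors made with a mean of 0 and an SD of 1 within each array. For 72.9% of its entries the z score lay within 0.0001 of a straight line of the log2 signal of the probe with that name. The other 27.1% are not, with r between 0.817 and 0.832 against the log2 signal, and how those entries were made is not given in the sources used here. For 28.9% of the tested genes the z score is such an entry. The signal table was used for all main values and the z scores for an alternative.

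Intensities were background-corrected and quantile normalized over all 16 arrays with neqc of limma 3.58.1 in R 4.3.3, which uses the detection p-values to model the background, and put on a log2 scale after an offset of 16. Log2 differences of neqc values are drawn toward 0 at low signal. A probe was used when its detection p was under 0.01 on at least 4 arrays, which 10550 probes met. Gene symbols and Entrez numbers came from the platform's probe annotation, which named 16850 probes (65.6%), and 8847 probes had no symbol. By Entrez number, all but 11 of the named probes matched a gene of the mouse annotation of assembly GRCm38.p6, and no coordinates were used. Among all named probes, detected or not, 312 genes had more than 1 probe. Where more than 1 detected probe named a gene, the probe with the highest mean log2 value was taken. With the 3914 detected probes that had no symbol left out, 6559 genes remained. For a gene undetected on all arrays of one group and detected in the other, a lower bound of the fold was computed, with each undetected array set at no less than the lowest log2 value of any probe detected on it.

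Each of the 16 arrays was entered in 1 limma fit with 4 groups and empirical Bayes moderation. The contrasts were HFD minus chow within chip A, HFD with NMN minus HFD within chip B, their sum for NMN against chow, and HFD on chip B minus HFD on chip A. P-values were adjusted over the 6559 genes by Benjamini and Hochberg, with 0.05 as the threshold, and SE values are the moderated ones of limma with n = 4 arrays per group. P-values of the permutation tests measure the spread between mice. Those of limma rest on 1 spread pooled over all 16 arrays as if independent, in which each HFD mouse counts with 2 arrays. The diet and NMN p-values of limma share this limit. With only the 8 arrays of the chip, an alternative, 406 genes passed for the diet and 0 for NMN. The contrast of the chips sets differences within mice against the pooled spread. The contrast of NMN with chow assumes that the HFD arrays of both chips stand for alike mice, and the 2 arrays of an HFD mouse count in it as separate arrays.

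Whether replicate numbers name the same animals was checked. The column names of the signal table give the HFD arrays of both chips the same 4 animal numbers, with deviations correlated at 0.765 to 0.892. No animal number is shared between the other groups. Arrays with the same number in chow and HFD on chip A gave r = -0.007, 0.072, 0.237 and 0.234, and in HFD and NMN on chip B r = -0.115, -0.275, -0.005 and 0.328. Values are therefore given without pairing, and the replicate number as a block is an alternative.

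The 35 gene lists (22 pathways and 13 cell types, 711 genes, 80 without a named probe), the tests, the alternatives of the processing and the rule for naming genes were fixed before the data were examined. The 30 lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, two-sided and adjusted over the 30 lists. Camera with a correlation estimated from the residuals, fry in its directional and mixed forms, and an exact permutation of list means over 70 assignments were run beside it. A count adjusted over the list alone uses the Benjamini and Hochberg adjustment among the members of that list. Named genes were, per contrast, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, or, where fewer than 5 passed in a direction, the 10 with the smallest p. Up to 4 members with the smallest p were also named in each list that was called or had at least 2 members past the threshold. Il1b, S100a8, S100a9, Gsta2, Gsta4, Dbp, Per1, Per2, Nampt, Sirt1 and Nnmt were named in every contrast.

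For the shift of diet-changed genes, the mean NMN effect on genes lower in HFD was subtracted from that on genes higher in HFD, with an exact two-sided permutation test over the 70 assignments of the 8 arrays of chip B. Pearson and Spearman correlations of the diet and NMN effects used the same assignments. The smallest p-value such a test can give is 0.0286.

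Alternatives were each chip normalized on its own, median centring, the z scores, no background correction, no detection filter, all probes, only the arrays of the chip, the replicate block, array weights, an intensity trend in the variance, divisions of the HFD mice into 2 and 2, and each mouse left out in turn. An HFD mouse was left out with its arrays on both chips. Those chosen after seeing the data were the 2 arrays of an HFD mouse as a random block (duplicateCorrelation, with statmod 1.5.0), 1 value per mouse, further divisions of the HFD mice, the replicate block for the chips, permutation of list means, and HFD mice 2 and 3 left out.

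The pipeline was tested on simulated data in 10 simulations. At a true diet difference of 0.5, 1 and 2 on the log2 scale, 70.7%, 93.9% and 98.7% of genes were recovered. At an NMN difference of 0.25, 0.5 and 1, the recovered share was 15.3%, 63.6% and 93.5%. Each simulation changed 200 genes, with noise drawn independently for each gene. These shares are therefore not the chance of finding such a change on the real arrays. Of the diet calls, 6.29% were false. Each moved list was called, and 0 of 200 unchanged lists, in genes simulated with no correlation between them. That gives no rate of false list calls for these arrays, where camera called a median of 9 lists in the other splits of the diet arrays and 9.5 in those of the NMN arrays. Detected probes per array ranged from 9473 to 10569, the background, the median signal of probes with a detection p over 0.5, from 29.5 to 39.0 and the ratio of mean signal to background from 5.18 to 6.85. The number of arrays limits the precision of every value. Probes with no symbol were left out of the tests of genes and lists.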

Results

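Liver RNA of female C57BL/6J mice was measured on 16 single-colour Illumina bead arrays, 4 for each of 4 groups. Chip A held 4 arrays of mice on regular chow and 4 arrays of mice on a high-fat diet (HFD). Chip B held 4 arrays of HFD mice and 4 arrays of HFD mice injected for 7 days with nicotinamide mononucleotide (NMN), a precursor of the coenzyme NAD. Each array had a mean signal of 202 over its 25697 probes, between 9473 and 10569 detected probes, and a mean signal 5.18 to 6.85 times its background. The number of arrays limits the precision of every value. Of the genes with a named probe, 6559 were detected on at least 4 arrays and tested.

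The HFD arrays of chip B held the RNA of the same 4 mice as the HFD arrays of chip A, so the study holds 12 mice. The column names of the signal table carry the same animal numbers on both chips, and the values matched them. Across genes, the deviation of a mouse from its group mean on chip A correlated with its deviation on chip B with r = 0.889, 0.892, 0.765 and 0.870 for HFD mice 1 to 4. Arrays of different HFD mice gave r between -0.644 and 0.198. Genes are not independent replicates. The median SD was 0.14 on the log2 scale between HFD mice within a chip. Between the 2 arrays of a mouse it was 0.07, after the mean difference between the chips was removed from each gene.

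The comparison on chip A asked which liver genes differed between HFD and chow mice, with 4 arrays in each group. Genes of cholesterol synthesis fell. Of 17 measured members of that list, 12 passed the test over all genes and 17 passed adjusted over the list alone. Sqle, which encodes squalene epoxidase, was 5.87-fold lower (log2 change -2.55, SE 0.41, adjusted p = 0.00305). The log2 changes were -2.28 (SE 0.36) for Cyp51, lanosterol demethylase, -2.27 (SE 0.32) for Msmo1, a sterol methyl oxidase, and -1.70 (SE 0.29) for Mvd, mevalonate diphosphate decarboxylase. Srebf2, the transcription factor that drives this pathway, fell by 0.64 (SE 0.09, adjusted p = 0.00178), and Hsd17b7 fell by 1.04 (SE 0.13). The list had a median change of -1.22 and an adjusted p = 1.6e-13 by camera, against an adjusted p = 0.352 with an estimated correlation. All 4 HFD mice lay below all 4 chow mice in the mean of the list (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give).

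Genes of lipid droplets and fat storage rose with the diet. Of 16 measured members, 8 passed over all genes and 10 adjusted over the list alone. Plin4, a coat protein of lipid droplets, was 6.40-fold higher (log2 change 2.68, SE 0.70, adjusted p = 0.0319). Apoa4, an apolipoprotein, rose by 2.42 (SE 0.40), Lpl, lipoprotein lipase, by 1.99 (SE 0.31), Pparg, a transcription factor of fat storage, by 0.98 (SE 0.17) and Hilpda by 0.62 (SE 0.10). The list's median change was 0.67, or 0.59 with the 2 members that were undetected in one group set at their lower bound. Its adjusted p was 7.1e-08 by camera, and the adjusted p = 0.207 with an estimated correlation. Among targets of PPAR alpha and genes of fatty acid oxidation, 4 of 22 rose, and 5 adjusted over the list alone. These included Fgf21, a fasting hormone of the liver (1.66, SE 0.38), Ehhadh, a peroxisomal enzyme (0.82, SE 0.23), Crat, carnitine acetyltransferase (0.80, SE 0.11), and Acaa1b (0.27, SE 0.08). The adjusted p of this list was 0.000439 by camera, and the adjusted p = 0.462 with an estimated correlation. In the lipogenesis list, 1 of 17 members rose, Elovl5 (0.84, SE 0.18), and 1 fell, Dgat2 (-0.49, SE 0.11), with the same counts adjusted over the list alone. The adjusted p for that list was 0.354.

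**Figure D1:**
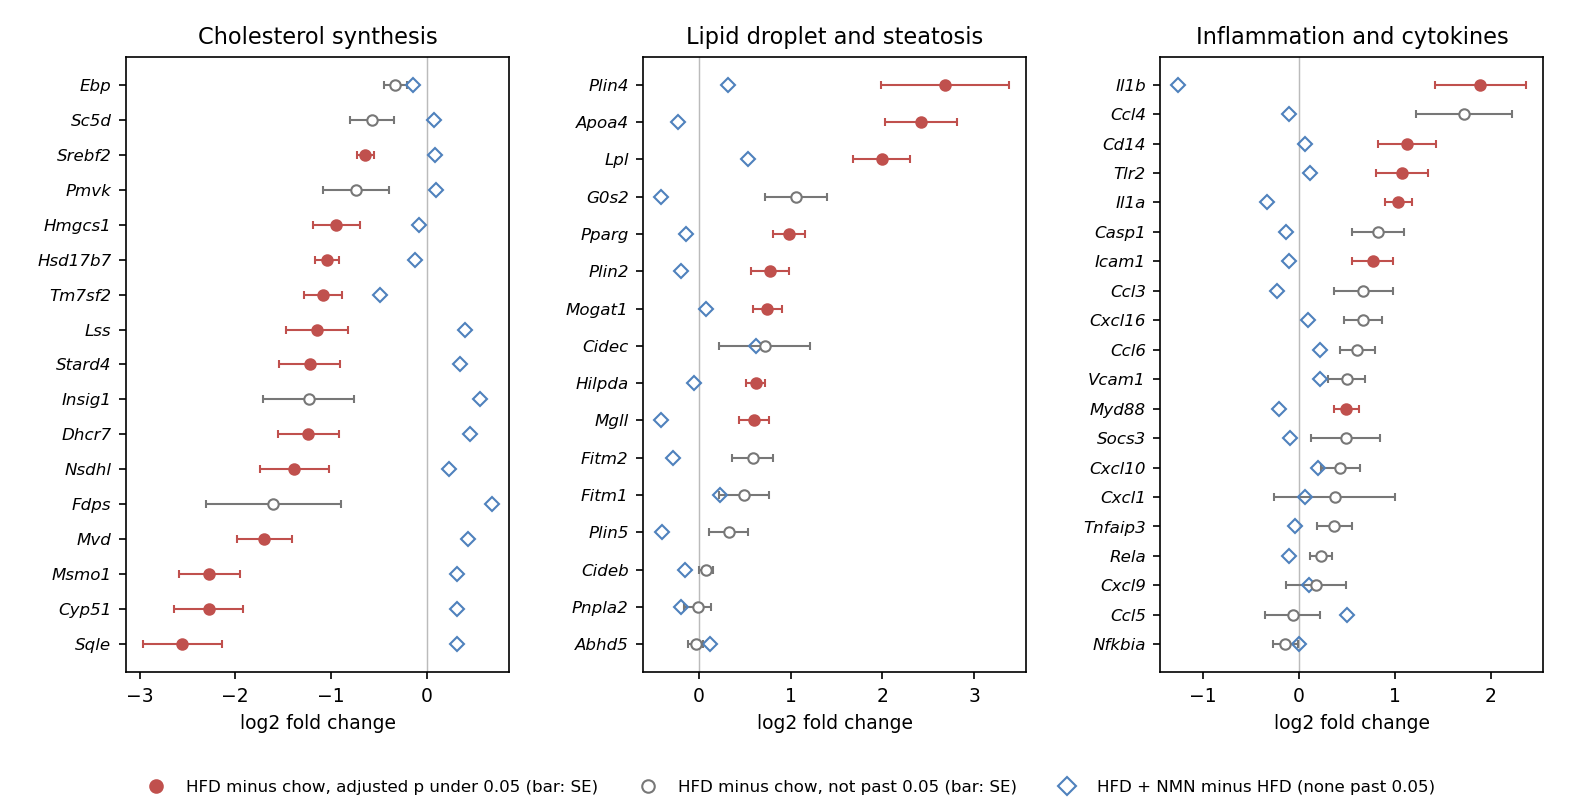
Log2 fold changes of each measured member of the cholesterol synthesis, lipid droplet and inflammation lists. Circles with bars give HFD minus chow with its SE, filled where the adjusted p was under 0.05, and open diamonds give HFD with NMN minus HFD, none of which passed; 12 of 17, 8 of 16 and 6 of 20 members are filled.

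Inflammation genes rose with the diet, and neutrophil genes stood high in 2 of the 4 HFD mice. Of 20 measured members of the inflammation and cytokine list, 6 rose over all genes and 11 adjusted over the list alone. Il1b, interleukin-1 beta, was 3.71-fold higher (log2 change 1.89, SE 0.48, adjusted p = 0.0275), Il1a rose by 1.04 (SE 0.14), Tlr2, a receptor for bacterial lipoproteins, by 1.07 (SE 0.27) and Cd14 by 1.12 (SE 0.30). The list's median was 0.55, or 0.49 with 2 members at their lower bound, and its adjusted p was 3.5e-07 by camera, against an adjusted p = 0.451 with an estimated correlation. Relative to the chow mean, the mean of the 9 measured neutrophil genes was 2.21 and 2.16 in HFD mice 2 and 3 on chip A, and 0.42 and 0.03 in HFD mice 1 and 4. In the same mice Il1b stood at 3.01 and 2.33, against 1.13 and 1.09. The mean of the inflammation list was 0.71, 1.07, 0.64 and 0.23 in HFD mice 1 to 4. None of the 9 neutrophil genes passed over all genes or adjusted over the list alone. S100a8, a calprotectin subunit, had a log2 change of 2.68 (SE 0.96, adjusted p = 0.0979) and S100a9 one of 2.03 (SE 0.79, adjusted p = 0.124). The neutrophil list's median was 1.01, or 0.48 with the 5 members undetected in one group at their lower bound and 0.64 without HFD mouse 2, and its adjusted p was 0.00268 by camera and the adjusted p = 0.462 with an estimated correlation. Fcgr4, an antibody receptor of myeloid cells, rose by 2.38 (SE 0.59) and Sirpb1a by 1.99 (SE 0.50).

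Markers of other liver cells differed by cell type. Among 9 macrophage genes, 2 rose over all genes and 5 adjusted over the list alone, namely Clec4f, a Kupffer cell lectin (0.98, SE 0.28), and Lyz2, lysozyme (1.65, SE 0.47) over all genes. That list had an adjusted p of 0.000456 by camera and an adjusted p = 0.462 with an estimated correlation. Its mean over chow was 1.59 and 1.13 in HFD mice 2 and 3, which had the high neutrophil values, and 0.52 and 0.44 in HFD mice 1 and 4. Among 12 endothelial genes, 2 rose and 4 adjusted over the list alone, with Lyve1 at 0.78 (SE 0.18) and Stab2 at 0.50 (SE 0.12). The adjusted p was 0.00268 by camera, and the adjusted p = 0.462 with an estimated correlation. The B cell list came down to 5 measured genes, of which 0 passed over all genes and 2 adjusted over the list alone (adjusted p of 0.0169 by camera, and adjusted p = 0.462 with an estimated correlation). Its members with the smallest p, Cd74 (0.85, SE 0.30, adjusted p = 0.0931) and H2-Ab1 (0.74, SE 0.28, adjusted p = 0.119), belong to antigen presentation by MHC class II, which macrophages and dendritic cells share. The mean of the B cell list was 1.01 and 0.83 in HFD mice 2 and 3, and 0.49 and 0.32 in HFD mice 1 and 4. Hepatocyte genes fell in 2 of 14 cases, Cps1 (-0.68, SE 0.19) and Ahsg (-0.22, SE 0.06), and in 4 adjusted over the list alone. The mean of the hepatocyte list over chow was -0.34, -0.23, -0.13 and -0.13 in HFD mice 1 to 4 on chip A. In the same mice on chip B it was -0.14, -0.13, -0.02 and 0.06, and chow mice were on chip A only. Normalized values of Ahsg repeated exactly between arrays, such as 0.009 over the chow mean in chow mice 1, 2 and 4, which limits its change and SE. Camera gave an adjusted p of 0.0294, and the adjusted p = 0.462 with an estimated correlation. Of 9 periportal genes 0 passed in either way, with Pck1 at -0.69 (SE 0.22, adjusted p = 0.0727). The list had an adjusted p of 0.00602 by camera and an adjusted p = 0.441 with an estimated correlation. Relative to the chow mean, Pck1 stood at -0.504, -0.925, -1.053 and -0.296 in HFD mice 1 to 4 on chip A. In the same mice on chip B it stood at 0.039, -0.735, -0.312 and 0.223. Of 11 pericentral genes 2 fell, Cyp1a2 and Gulo (-0.46, SE 0.11), and 3 adjusted over the list alone. By camera its adjusted p was 0.0465, and the adjusted p = 0.462 with an estimated correlation. The hepatocyte call was lost without chow mouse 3 or HFD mouse 1 (adjusted p = 0.0501 and 0.0768) and the pericentral hepatocyte call without chow mouse 1, chow mouse 3 or HFD mouse 4 (adjusted p = 0.163, 0.0501 and 0.0779).

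Drug-metabolising and male-biased genes moved in both directions, and the bile acid and female-biased genes that passed over all genes fell. Cyp1a2 fell by 1.93 (SE 0.22) and Cyp2b10 by 2.24 (SE 0.43), while Cyp3a11 rose by 0.49 (SE 0.12). These were the 3 of 18 xenobiotic genes that passed, and adjusted over the list alone 1 rose and 3 fell. The adjusted p was 0.0294 by camera, and the adjusted p = 0.462 with an estimated correlation. The xenobiotic call was lost without chow mouse 1 or 4 (adjusted p = 0.116 and 0.0946) and without HFD mouse 2 or 3 (adjusted p = 0.0934 and 0.0614). Of 18 bile acid genes 4 fell: the bile salt export pump Abcb11 (-0.61, SE 0.14), the uptake transporters Slco1a4 (-0.84, SE 0.21) and Slc10a1 (-0.41, SE 0.10), and Cyp7b1 (-0.50, SE 0.11). Adjusted over the list alone, 1 rose and 5 fell, and the list had an adjusted p of 0.0824 by camera. In these female mice, 2 of 9 genes of the female-biased list fell, and 2 adjusted over the list alone: A1bg (-2.59, SE 0.67) and Cux2, a transcription factor of the female liver (-1.68, SE 0.29). Camera gave an adjusted p of 0.0116, and the adjusted p = 0.451 with an estimated correlation. In the male-biased list 4 of 10 fell, among them Serpina1e (-1.86, SE 0.33) and Mup20, a urinary protein (-0.80, SE 0.16), and Cyp2d9 rose (1.47, SE 0.31). Mup20 was 1.25 higher on chip B than on chip A in the same HFD mice, a larger difference than its change with the diet. Chow mice were on chip A only. Adjusted over the list alone, 1 rose and 5 fell. By camera its adjusted p was 0.0131, and the adjusted p = 0.207 with an estimated correlation.

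Of 17 measured genes of endoplasmic reticulum stress, 3 fell over all genes and 8 adjusted over the list alone, and in all 11 changes were negative and 6 positive. The 3 encode chaperones and a disulfide isomerase of that compartment: Hyou1 (-0.77, SE 0.12), Pdia4 (-0.58, SE 0.15) and Hsp90b1 (-0.54, SE 0.14), for an adjusted p of 0.0217 by camera and an adjusted p = 0.462 with an estimated correlation. Of 11 immediate early genes, Fos rose by 0.97 (SE 0.19), Jun rose by 0.55 (SE 0.14) and Zfp36 fell by 0.51 (SE 0.13), and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.125). Of 14 clock genes, Nr1d1 fell by 0.87 (SE 0.25) and Rora fell by 0.36 (SE 0.10), and 2 rose and 4 fell adjusted over the list alone (adjusted p = 0.147). Noct, a clock-driven gene outside that list, fell by 1.82 (SE 0.44). In the glucose list Ppargc1a, a coactivator of gluconeogenesis, fell by 0.55 (SE 0.15), the only one of 16 members to pass over all genes, against 1 rise and 4 falls adjusted over the list alone. The adjusted p was 0.0270 by camera, and the adjusted p = 0.462 with an estimated correlation. In the list of NAD metabolism, 1 of 16 genes fell, also adjusted over the list alone: Aox3, an aldehyde oxidase (-0.66, SE 0.14). Camera gave an adjusted p of 0.0338, and the adjusted p = 0.462 with an estimated correlation. Of 19 interferon genes, Oas1g rose by 0.72 (SE 0.17), and 4 rose and 2 fell adjusted over the list alone. By camera its adjusted p was 0.0338, and the adjusted p = 0.462 with an estimated correlation. With chow mouse 4 left out the list calls for ER stress and for gluconeogenesis were lost (adjusted p = 0.0672 and 0.0787). The NAD metabolism call was lost without chow mouse 1, chow mouse 3 or HFD mouse 1 (adjusted p = 0.0592, 0.0725 and 0.105), and the interferon response call without chow mouse 1, 2 or 4 or HFD mouse 3 (adjusted p = 0.0596, 0.166, 0.0946 and 0.0987).

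The other lists were not called for the diet. Sirtuins gave 0 of 5 (Sirt1 0.07, SE 0.13; adjusted p = 0.442 for the list), oxidative phosphorylation 0 of 38 (adjusted p = 0.787), ribosomal proteins 0 of 21 (adjusted p = 0.102), proliferation 0 of 8 (adjusted p = 0.153) and stellate cells and fibroblasts 0 of 9 (adjusted p = 0.231), and adjusted over the list alone also 0. For oxidative phosphorylation the median of 0.01 and the mean of -0.01 differed in sign. A single member passed in the heat shock list of 10 (Stip1, -0.53, SE 0.13; adjusted p = 0.695 for the list), the glutathione and oxidative stress list of 29 (Hmox1, 0.89, SE 0.22; adjusted p = 0.117) and the acute phase list of 20 (Hpx, 0.30, SE 0.07; adjusted p = 0.137), also adjusted over the list alone. Hmox1, heme oxygenase, and Hpx, hemopexin, were chosen after their values were seen. Lists of T and NK cells, cholangiocytes, erythroid cells, adipocytes and acinar pancreas had fewer than 5 measured members and were not tested. Single genes outside the lists included Ly6d, undetected on the chow arrays and at least 5.80-fold higher on the HFD arrays, Gpc1, a glypican (2.79, SE 0.43), Esm1 (1.99, SE 0.43) and Wfdc2 (1.96, SE 0.22). Of the genes fixed by name, Gsta2 (-0.96, SE 0.41, adjusted p = 0.160), Gsta4 (-0.84, SE 0.29, adjusted p = 0.0920), Dbp (-1.60, SE 1.02, adjusted p = 0.348), Per1 (-0.55, SE 0.18, adjusted p = 0.0793) and Nnmt (-0.44, SE 0.24, adjusted p = 0.259) did not pass. Dbp stood at -0.87 without HFD mouse 2 and at -2.43 without HFD mouse 4, and Nnmt at -0.29 without chow mouse 4. Probes for Per2 and Nampt were detected on 0 arrays.

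In all, 452 of 6559 genes differed between HFD and chow in limma, 207 higher and 245 lower, 67 of them by more than 1 on the log2 scale, and 1661 had an unadjusted p under 0.05. The arrays of HFD and chow did not overlap for 1005 genes, or 15.3%, where chance gives 2.86%. The count was 209, 288 and 208 without chow mouse 1, 2 or 4, 217 and 175 without HFD mouse 2 or 3, 99 without both HFD mice 2 and 3 (chosen after seeing the data), 259 with no filter on detection and 780 with estimated array weights. Without HFD mice 2 and 3, 11 of the 18 lists were called, and the calls were lost for the neutrophil, B cell, interferon response, xenobiotic, ER stress, gluconeogenesis and pericentral hepatocyte lists (adjusted p = 0.295, 0.227, 0.295, 0.425, 0.135, 0.0916 and 0.0801). Of the 58 genes called for the diet under the naming rule, 23 passed in each planned refit and with each mouse left out, among them Sqle, Cyp51, Msmo1, Mvd, Srebf2, Apoa4, Lpl, Pparg, Crat, Il1a, Cyp1a2, Cyp2b10 and Cux2. Plin4 did not pass without any 1 of the 4 chow mice or HFD mouse 2 or 3 (adjusted p up to 0.0788), nor Il1b without chow mouse 1, 2 or 4 or HFD mouse 3 (adjusted p up to 0.0922), Ly6d without chow mouse 1, 2 or 4 or HFD mouse 2 (adjusted p up to 0.0717), or A1bg without chow mouse 2 or 3 or any 1 HFD mouse (adjusted p up to 0.0855). With 1 of 8 mice left out in turn, the call was lost in 8 fits for Ahsg (adjusted p up to 0.140), in 7 for Acaa1b, Cd14, Clec4f and Cps1 (up to 0.131), in 6 for Ehhadh, Jun, Lyz2, Nr1d1, Pdia4, Ppargc1a, Slco1a4 and Tlr2 (up to 0.145), in 5 for Hsp90b1, Noct, Oas1g and Rora (up to 0.144), in 4 for Dgat2, Sirpb1a, Stab2 and Zfp36 (up to 0.0937), in 3 for Abcb11, Cyp3a11, Fcgr4, Lyve1 and Slc10a1 (up to 0.0966), in 2 for Fgf21 and Gulo (up to 0.0779) and in 1 for Aox3, Cyp7b1 and Elovl5 (up to 0.0590).

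The comparison on chip B asked what 7 days of NMN changed in the liver of HFD mice, with 4 arrays in each group. No gene passed in limma. The smallest adjusted p was 0.158, and 643 genes had an unadjusted p under 0.05, where 328 would be the mean count if no gene differed. Genes are not independent, and 4 of 35 splits of these 8 arrays, the real one included, gave at least as many. The highest other split had 895, in a count chosen after seeing the data. Among the lower values were Irs2, an adaptor of the insulin receptor (-0.90, SE 0.17), Slc25a25, a mitochondrial carrier (-0.77, SE 0.15), Prodh2 (-0.68, SE 0.14) and Dct (-1.23, SE 0.28). Among the higher values were Tspan8 (0.95, SE 0.19), Mlkl, an effector of necroptosis (0.72, SE 0.15), Fkbp5, a gene induced by glucocorticoids (0.68, SE 0.15), and Lrrc14b (0.69, SE 0.15). For each of these the 4 arrays with NMN lay on one side of all 4 without it, as they did for 321 genes, or 4.89%, where chance gives 2.86% on average. How far this share varies between splits was not counted. The adjusted p of the 10 highest-ranked and 10 lowest-ranked genes lay between 0.158 and 0.162. The number passing was 4 without HFD mouse 1 (Hyi -0.68, Lrrc14b 0.81, Mme -0.90 and Tspan8 1.11) and 3 without NMN mouse 4 (Irs2 -1.03, Letmd1 -0.43 and Slc25a25 -0.93). Hyi and Mme were chosen after their values were seen.

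Several lists had higher values with NMN in camera, with 0 members past the test over all genes. In the heat shock list, 5 of 10 members passed adjusted over the list alone, with Hspb1 at 0.82 (SE 0.22), Dnajb1 at 0.53 (SE 0.18), Bag3 at 0.47 (SE 0.16) and Stip1 at 0.41 (SE 0.13). The adjusted p of that list was 2.1e-05 by camera and the adjusted p = 0.609 with an estimated correlation. In the glutathione list of 29 genes, 2 passed adjusted over the list alone, and Gsta2, a glutathione transferase, stood at 1.48 (SE 0.41, adjusted p = 0.221), Gstp1 at 0.68 (SE 0.17) and Nqo1 at 0.53 (SE 0.17). Its adjusted p was 0.00356 by camera and the adjusted p = 0.609 with an estimated correlation. Both lists reached an exact permutation p of 0.0286 in their means, the smallest possible, and neither passed across the 30 lists. Among 17 genes of endoplasmic reticulum stress, 0 passed adjusted over the list alone, with Herpud1 at 0.48 (SE 0.18) and Hsp90b1 at 0.40 (SE 0.14), for an adjusted p of 0.00133 by camera and an adjusted p = 0.682 with an estimated correlation. Among 17 lipogenic genes, 2 passed adjusted over the list alone. Scd2 was undetected on the HFD arrays and at least 1.33-fold higher with NMN, Dgat2 stood at 0.41 (SE 0.11) and Thrsp at 1.47 (SE 0.85), or 0.56 without HFD mouse 1. The adjusted p was 0.0221 by camera and the adjusted p = 0.83 with an estimated correlation. On chip B, Thrsp stood at -2.94 relative to the chow mean in HFD mouse 1, and at 0.24, 0.85 and 1.12 in HFD mice 2 to 4. Without HFD mouse 1 the median of the list was 0.0021, against 0.34 with it. The lipogenesis call was lost without HFD mouse 1, NMN mouse 3 or NMN mouse 4 (adjusted p = 0.711, 0.197 and 0.0950).

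Among 14 clock genes, 3 stood higher and 1 lower with NMN adjusted over the list alone. Dbp, an output gene of the clock, had a log2 difference of 2.34 (SE 1.02, adjusted p = 0.463), Ciart of 1.14 (SE 0.35), Bhlhe40 of 0.65 (SE 0.17), Nfil3 of -1.03 (SE 0.26) and Per1 of 0.41 (SE 0.18). The adjusted p of the list was 0.0488 by camera and the adjusted p = 0.682 with an estimated correlation. Dbp spanned 4.68 on the log2 scale among the HFD mice of chip A, 3.33 among the chow mice and 0.70 among the NMN mice. The list of PPAR alpha targets and fatty acid oxidation had lower values, with 0 of 22 adjusted over the list alone, Pdk4, which inhibits pyruvate oxidation, at -1.03 (SE 0.33) and Crat at -0.35 (SE 0.11). Its adjusted p was 0.000645 by camera and the adjusted p = 0.682 with an estimated correlation. Without HFD mouse 1 the call for PPAR alpha and fatty acid oxidation was lost (adjusted p = 0.194). The circadian clock call was lost without HFD mouse 1, 2 or 3 (adjusted p = 0.0886, 0.192 and 0.101) and without NMN mouse 1, 2 or 4 (adjusted p = 0.0547, 0.184 and 0.0900).

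Cell type lists also differed on chip B in camera. The 9 neutrophil genes had a median of -0.90, or -0.54 with 4 of them at their bound, an adjusted p of 0.000988 by camera and an adjusted p = 0.682 with an estimated correlation. Mpo, undetected on the NMN arrays, stood at least 1.45-fold lower, S100a8 stood at -1.55 (SE 0.96) and S100a9 at -1.37 (SE 0.79). Their mean was 2.21 and 2.17 over chow in HFD mice 2 and 3, 0.41 and -0.01 in HFD mice 1 and 4, and 0.69, 0.17, 0.15 and 0.08 in NMN mice 1 to 4. Il1b had a difference of -1.26 (SE 0.48, adjusted p = 0.393). Without HFD mouse 2 the differences were -0.83 for Il1b, -0.92 for S100a8 and -0.86 for S100a9, without HFD mouse 3 -1.0 for S100a8 and -0.86 for S100a9, and without HFD mouse 4 -2.40 and -2.08. The median of the neutrophil list was -0.54 without HFD mouse 2. Without HFD mice 2 and 3, an alternative chosen after seeing the data, the median of the neutrophil list was 0.07. Of 12 endothelial genes, Dnase1l3 stood at -0.32 (SE 0.13), for an adjusted p of 0.00837 by camera and an adjusted p = 0.682 with an estimated correlation. The 5 genes of the B cell list, with Cd74 at 0.66 (SE 0.30) and H2-Eb1 at 0.61 (SE 0.30), had an adjusted p of 0.00837 by camera and an adjusted p = 0.682 with an estimated correlation. Without NMN mouse 3, Cd74 stood at 0.37 and H2-Eb1 at 0.24. Of 9 stellate cell and fibroblast genes, Timp1, an inhibitor of matrix proteases, stood at 1.01 (SE 0.30) and Dpt at 0.57 (SE 0.20), with 2 passing adjusted over the list alone, and Dpt at 0.37 without NMN mouse 3. Camera gave an adjusted p of 0.0191, and the adjusted p = 0.682 with an estimated correlation. The endothelial call was lost without HFD mouse 2 or NMN mouse 3 (adjusted p = 0.103 and 0.0944), the B cell call without HFD mouse 1 or NMN mouse 3 (adjusted p = 0.0685 and 0.245), and the stellate and fibroblast call without HFD mouse 1, HFD mouse 4, NMN mouse 2 or NMN mouse 3 (adjusted p = 0.0671, 0.0950, 0.0555 and 0.159).

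Without HFD mice 2 and 3, 9 lists were called with NMN, some of them not among the 10 called with all mice. Of those 10, the calls were lost for the neutrophil, circadian clock, glutathione, ER stress and endothelial lists (adjusted p = 0.587, 0.568, 0.0727, 0.124 and 0.230). The remaining 20 lists had adjusted p values between 0.123 and 0.959 in this comparison. NAD metabolism had a median of 0.04 (adjusted p = 0.831) and sirtuins one of -0.04 (adjusted p = 0.351), with Sirt1 at -0.10 (SE 0.13) and Nnmt at -0.20 (SE 0.24). Gsta4 stood at 0.20 (SE 0.29). Adjusted over the list alone, 1 xenobiotic gene stood higher and 1 lower, 1 female-biased gene higher and 2 lower, 2 male-biased genes higher and 1 lower, 1 immediate early and 1 pericentral gene higher and 2 genes of the glucose list lower. The median differed in sign from the mean or the test for the glucose, acute phase and immediate early lists. With 1 mouse left out Sirt1 ranged from -0.15 to -0.03, Nnmt from -0.32 to 0.03 and Gsta4 from -0.03 to 0.44. Cholesterol synthesis genes had a median of 0.31 (adjusted p = 0.321), with list means of -2.12 in HFD mouse 1, -0.83, -0.92 and -1.34 in HFD mice 2 to 4, and -1.31, -1.25, -0.88 and -0.96 in NMN mice 1 to 4. The other medians were -0.14 for lipid droplet genes (adjusted p = 0.389) and -0.01 for inflammation genes (adjusted p = 0.781).

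**Figure D2:**
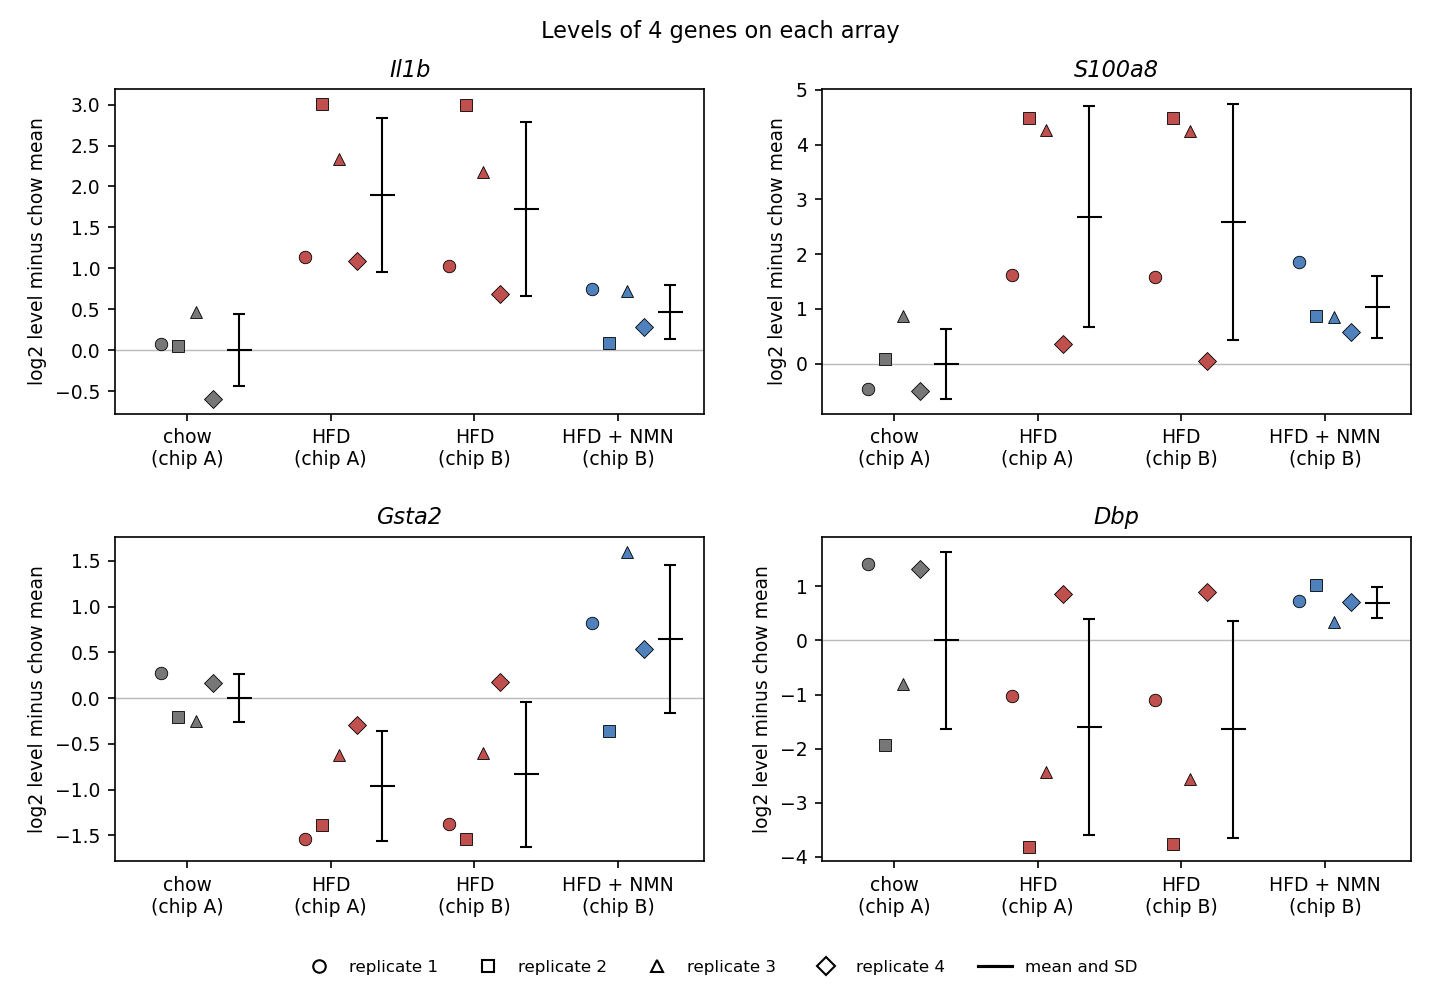
Log2 levels of Il1b, S100a8, Gsta2 and Dbp on each of the 16 arrays, relative to the mean of the chow arrays. Symbols give the replicate number, and bars the mean and SD of 4 arrays; Il1b stood at 3.01 and 2.33 in HFD mice 2 and 3, and Dbp spanned 4.68 among the HFD mice of chip A and 0.70 among the NMN mice.

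Whether NMN moved the diet-changed genes back toward chow was asked with genes chosen on chip A and tested on chip B. The HFD mice of chip B are the same mice that chose the genes. That pulls the shift below 0 and the shares of opposite signs up, except where different HFD mice serve for the 2 sides. Of the 207 genes higher in HFD, 114 (55.1%) had an opposite sign with NMN, and their median change was 0.57 with the diet and -0.03 with NMN. Of the 245 genes lower in HFD, 117 (47.8%) had an opposite sign, with medians of -0.50 and -0.01. At an unadjusted limma p under 0.05 with NMN, 23 of the higher genes had the opposite sign and 10 the same. Of the lower genes, 25 had the opposite sign and 16 the same at that threshold. A diet score, the mean of the higher genes minus the mean of the lower genes, was 1.35 (SD 0.15, n = 4) in HFD mice on chip A, where the genes were chosen, and 1.31 (SD 0.15, n = 4) in the same mice on chip B. With NMN it was 1.28 (SD 0.29, n = 4), and in chow mice 0, the reference (SD 0.09, n = 4). The shift with NMN was -0.03 (exact two-sided permutation p = 0.857 over 70 assignments), -2.36% of the diet difference. The shift was 0.12 without NMN mouse 4, 0.01 without NMN mouse 2, and -0.51 without HFD mice 2 and 3 (exact p = 0.0667, the smallest that design allows, chosen after seeing the data), where the remaining HFD mice both choose the genes and serve as controls. With different HFD mice for the diet and for the NMN side, the 6 ways to halve the HFD mice gave 0.25 (172 genes higher and 196 lower with the diet), 0.20 (26 and 34), 0.27 (67 and 68), 0.18 (309 and 194), -0.45 (2 and 5) and -0.06 (16 and 19).

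**Figure D3:**
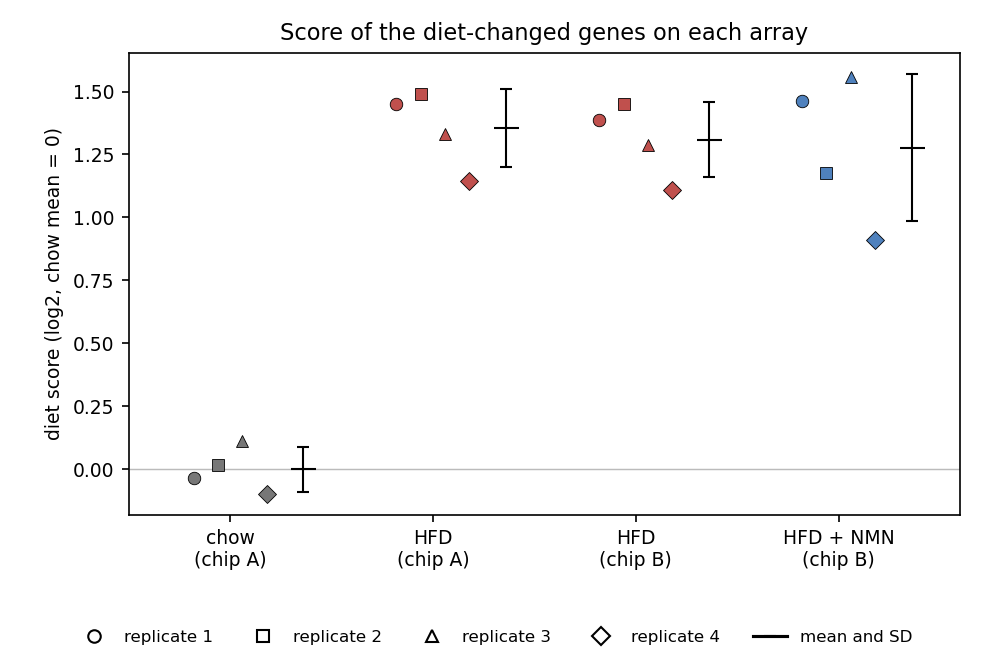
The diet score of each array, the mean log2 level of genes higher in HFD minus that of genes lower in HFD, with the chow mean at 0. Symbols give the replicate number and bars the mean and SD of 4 arrays; NMN mice averaged 1.28 and HFD mice 1.31 on chip B.

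Across genes, the diet and NMN effects had a Pearson r of -0.116 (exact permutation p = 0.80) and a Spearman rho of -0.02 (exact permutation p = 0.971). Their covariance was -0.00734. The HFD mice enter both effects with opposite sign, and the spread between these mice alone gives an expected covariance of -0.0127.

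The comparison of NMN mice with chow mice, taken through the HFD mice held on both chips, found 104 genes in limma, 41 higher and 63 lower, and 1156 at an unadjusted p under 0.05. Wfdc2 differed by 2.20 (SE 0.30), Lpl by 2.53 (SE 0.44) and Cyp2d9 by 1.94 (SE 0.44), all higher with NMN. Lower were Cyp2b10 (-3.28, SE 0.61), A1bg (-4.59, SE 0.95), Cyp1a2 (-2.04, SE 0.31), Msmo1 (-1.95, SE 0.46), Hsd17b7 (-1.16, SE 0.18), Irs2 (-1.08, SE 0.24) and Srebf2 (-0.55, SE 0.13). Of 17 cholesterol synthesis genes, 4 were lower over all genes and 9 adjusted over the list alone, with an adjusted p of 5.6e-09 by camera and an adjusted p = 0.477 with an estimated correlation. Of 16 lipid droplet genes, 1 was higher over all genes and 6 adjusted over the list alone, with an adjusted p of 8.3e-05 by camera and an adjusted p = 0.477 with an estimated correlation. Of the genes changed by the diet, 30 of 207 and 51 of 245 also differed between NMN and chow, and 138 of 207 and 163 of 245 with the 2 arrays of an HFD mouse as a random block. Over all 6559 genes, 104 and 745 differed in these fits. The contrast of NMN with chow contains the diet contrast that chose these genes. Part of the overlap is therefore built in, and it does not show that diet changes persisted with NMN. In all, 12 of 30 lists were called, 7 higher and 5 lower, and 0 with an estimated correlation. The count of genes moved from 104 to 38, 44 and 20 without chow mouse 1, 2 or 4, to 44, 17, 0 and 10 without HFD mouse 1, 2, 3 or 4, and to 14, 15 and 265 without NMN mouse 1, 3 or 4. It was 745 with the 2 arrays of an HFD mouse as a random block, 44 with the replicate block, 13 with no filter and 1 without HFD mice 2 and 3.

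The HFD mice measured on both chips showed how far the chips differed. In limma, 3 genes were higher on chip B: Mup20 (1.25), H2-Q10 (0.82) and Bcap31 (0.52). With the arrays paired by mouse, as a replicate block, 10 genes passed, all higher on chip B, among them Alb (0.61), Serpinc1 (0.60) and Mup20 (1.25). With the mouse as a random block over all 16 arrays, 319 genes passed, 234 higher and 85 lower. Genes named here other than Mup20 and Alb were chosen after their values were seen. The diet and NMN comparisons each lie within a chip.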

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

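The tests of explanations and the counts over other splits of the arrays in this part were chosen after the results were seen. Across genes the diet and NMN effects had an r of -0.116 (exact permutation p = 0.80), which shows no opposite direction. The HFD mice shared by both comparisons pull this r below 0, and with different HFD mice on each side the mean r over 6 divisions was 0.057. The shift with NMN is a mean over the diet-changed genes, so a return of single genes is not excluded. A mean return of at least 50% of the diet difference would be a shift of -0.68. The shift of -0.032 (SE 0.165) over all 8 arrays of chip B argues against that. With HFD mice 2 and 3 left out it was -0.51, but there HFD mice 1 and 4 both choose the genes and serve as controls, which pulls the shift below 0; with these pairs of mice on different sides it was 0.27 and 0.18. The division that gave -0.45 rests on 2 higher and 5 lower genes, and a smaller movement in either direction stays open.

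Neutrophil genes stood high in HFD mice 2 and 3. A fault of single arrays is argued against, since the list mean differed by at most 0.045 between the 2 arrays of a mouse, against a gap of 1.74 to the other HFD mice. A rise was not seen in HFD mouse 4, at 0.033 on chip A against 0.24 in the highest chow mouse. HFD mouse 1 stood at 0.42, above that chow mouse. Most of these genes were undetected in chow, so a small rise in every HFD mouse stays open. More blood left in the liver piece would raise Alas2, a red cell transcript, along with the list, but Alas2 stood at most 0.49 over chow in these mice, against list rises of 2.13 and 1.83, with Hba-a1 at 0.42 and 0.45 and Hbb-bt at 0.67 and 0.71 on chip A, while Slc4a1, another red cell gene, stood at 2.25 and 3.02. HFD mouse 4, with no neutrophil rise, had Alas2 at 0.83, Hba-a1 at 0.83 and Hbb-bt at 0.78. The mean of the 4 measured erythroid genes, Slc4a1 included, was 0.40, 0.72, 1.17 and 0.92 in HFD mice 1 to 4 on chip A.

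The NMN values of the 14 clock genes, 0 of which passed over all genes, lay along the axis on which the chow mice differed among themselves. They correlated with that axis with r = 0.959, at percentile 99.8 of random lists. Clock genes vary together, so any cause that shifts the clock could lie along this axis. Different times of day at collection are a candidate explanation, which the percentile does not favour over others. The diet effect on the 14 genes correlated with the same axis at r = -0.922, so their diet values are open to this explanation too. The weight on the axis was 0.66 for Dbp. Nr1d1 and Rora, which fell with the diet, had weights of 0.13 and 0.016, and a small weight does not exclude the explanation. Clock scores on chip A were -1.63, -4.84, -3.36 and 0.48 in HFD mice 1 to 4, and 2.38, -2.19, -1.96 and 1.76 in the chow mice. An effect of NMN cannot be told apart from different times of day, with an exact permutation p of 0.0571 for the clock score and no collection times given in the sources used here.

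Other splits of the same arrays were counted. For the 452 genes called for the diet, the real split alone gave as many (1 of 35 splits, highest other 0). That argues against chance but is the smallest share that 35 splits allow, so it does not exclude it. For the 18 lists called for the diet, 1 of 35 splits gave as many, but the highest other had 17 and the median of the others was 9, and camera with an estimated correlation called 0, so chance is not taken as excluded. It cannot be excluded for NMN, with 643 genes at an unadjusted p under 0.05 (4 of 35 splits, highest other 895) and 10 lists (18 of 35 splits, highest other 17). With 0 genes called for NMN in limma, 35 of 35 splits have as many by construction (highest other 0), which decides nothing. The splits also decide nothing for the 1161 genes between NMN and chow on 1 value per mouse (1 of 35 splits, highest other 1), since an error in the chip correction falls on the real split alone. For the 3 genes between the HFD arrays of the chips, 3 of 35 splits gave as many, and the highest other had 485, a split that put both arrays of a mouse on the same side and so points to the structure of the samples. Of the 8 splits that part the arrays of every mouse, the highest of the others had 0 genes, and 8 splits are too few for a share under 0.05.

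Of 688 groups of 4 arrays tested for a value far from the other 3, 40 held one, where chance gives 5%. The gap to the nearest array, as a share of the group's range, is given for each. This share does not depend on the size of the range, so it also flags small differences. For Mpo, the chow arrays lay between -0.023 and 0.055 on the log2 scale relative to the chow mean. On chip B, HFD mouse 1 stood highest for Adck5 (0.933), Dnajc3 (0.959), Plin4 (0.875) and the means of the lipid droplet (0.881) and ER stress lists (0.909), and lowest for Ass1 (0.962), Lrat (0.861), Scd1 (0.886) and the lipogenesis list (0.852). On chip A it stood highest for Nnmt (0.836), Plin4 (0.889) and the lipid droplet list (0.986), and lowest for the lipogenesis list (0.865). Chow mouse 2 stood highest for Fos (0.863), Gstp1 (0.835), Mpo (0.830) and Tspan8 (0.859). Chow mouse 3 stood highest for Ngp (0.948) and Oas1g (0.853), and lowest for Ahsg (1), Gsta4 (0.841), Irs2 (0.841) and Per1 (0.855). The share of 1 for Ahsg arises because chow mice 1, 2 and 4 held the same value, 0.009 over the chow mean, against -0.028 in chow mouse 3. Chow mouse 4 was lowest for Scd1 (0.938). HFD mouse 3 on chip A was lowest for Ext1 (0.843) and Lyve1 (0.846), and on chip B highest for the female-biased list (0.833). HFD mouse 2 on chip B was highest for Dcn (0.922), and HFD mouse 4 for Foxo1 (0.861) and Per1 (0.857). NMN mouse 1 was highest for Camp (0.862), Ltf (0.839) and the neutrophil list (0.857), NMN mouse 2 for Aox3 (0.863), and NMN mouse 3 lowest for Prodh2 (0.928). NMN mouse 4 was highest for As3mt (0.830) and lowest for Esm1 (0.831), Hilpda (0.842), Hspb1 (0.845) and Vasn (0.905).

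Of 3914 detected probes with no gene symbol, 224 changed with the diet, 89 higher and 135 lower, beside 441 probes with a symbol in the same fit.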

How the results depend on the processing

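The fits with the mouse as a random block, 1 value per mouse, permutation of list means, the further divisions of the HFD mice, the replicate block for the chips, and HFD mice 2 and 3 left out were chosen after the results were seen. Genes changed by high-fat diet numbered 452. The count was 259 with no filter, which tests more genes, 780 with arrayWeights, 99 with HFD mice 2 and 3 left out, and 175 (without HFD mouse 3) to 564 (without HFD mouse 4) with 1 mouse left out. Under the other settings it lay within 1.5 times. Genes changed by NMN numbered 0 in limma (643 at an unadjusted p under 0.05), 1 with HFD mice 2 and 3 left out (Gpc1, -1.47) and 0 to 4 with 1 mouse left out, the 4 without HFD mouse 1. Genes differing between NMN and chow numbered 104, and 57 with median centring, 61 with the z scores of the series matrix, 13 with no filter, 44 with the replicate block, 197 with arrayWeights, 745 with the same-mouse block, 1161 on 1 value per mouse, which leaves out the error of the chip difference, 1 with HFD mice 2 and 3 left out, and 0 (without HFD mouse 3) to 265 (without NMN mouse 4) with 1 mouse left out. Only the 8 arrays of the chip gives no value for this comparison. High-fat diet arrays of the chips differed in 3 genes, 6 with each chip normalized on its own, 10 with the paired replicate block and 319 with the same-mouse block. Lists called for the diet numbered 18, and 0 with camera with estimated correlation, 6 with fry, directional, 0 with exact permutation of list means, 11 with HFD mice 2 and 3 left out and 10 with fry in the same-mouse block. Lists called for NMN numbered 10, and 0 with camera with estimated correlation, 0 with fry, directional, 0 with fry, mixed, and 0 with exact permutation of list means. With 1 mouse left out, 14 to 21 lists were called for the diet and 5 (without HFD mouse 1) to 13 (without HFD mouse 4) for NMN. The replicate block gave 442 genes for the diet, 0 for NMN, and 19 and 10 lists.

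The shift of diet-changed genes was -0.03, 0.011 in the opposite direction with only the 8 arrays of the chip, and 0.25, 0.20, 0.27 and 0.18 in the divisions of the HFD mice with HFD 1 and 2, 1 and 3, 1 and 4, or 2 and 3 on the diet side. It was -0.24 (without HFD mouse 4) to 0.12 (without NMN mouse 4) with 1 mouse left out, and 0.0052 without NMN mouse 2. It was -0.51 with HFD mice 2 and 3 left out, where the remaining HFD mice both choose the genes and serve as controls, -0.45 with HFD 2 and 4 on the diet side (2 higher and 5 lower genes) and -0.06 with HFD 3 and 4. The correlation of effects was 0.22, 0.038 and 0.24 in the divisions with HFD 1 and 2, 1 and 4, or 2 and 3 on the diet side. With HFD mice 2 and 3 left out, the NMN values turned positive for Mpo (0.012), Camp (0.075), S100a8 (0.23), S100a9 (0.16) and the neutrophil list (0.075). The diet value of Sirt1 ranged from -0.043 (without chow mouse 1) to 0.17 (without chow mouse 2). The NMN value of Gsta4 ranged from -0.026 (without HFD mouse 1) to 0.44 (without HFD mouse 4), that of Nnmt from -0.32 (without NMN mouse 4) to 0.030 (without NMN mouse 3), and that of the lipogenesis list was 0.0021 (without HFD mouse 1). Of the other diet values for named genes under planned settings other than leaving out 1 mouse, 956 had the same direction and side of the threshold, 73 no longer passed and 30 newly passed. With 1 mouse left out, 597 had the same, 162 no longer passed, 24 newly passed and 1 reversed. Other than where the construction shows it, the cause was not tested. The signal over background of 5.18 to 6.85 limits genes near the background, such as the neutrophil genes, most of which were undetected in chow.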

Other observations

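The lists and genes below were chosen after their values were seen, and the values per mouse were not tested. HFD mouse 1 had the highest acute phase and the lowest lipogenic values of the HFD mice among the genes given here. Relative to the chow mean, its acute phase genes Lcn2, lipocalin-2, and Saa1, serum amyloid A, stood at 4.67 and 3.21 on chip A and at 4.56 and 3.44 on chip B, and Orm2 at 1.72 and 1.63. In HFD mice 2 to 4 on chip A, Lcn2 stood at 3.01, 0.93 and -0.05 and Saa1 at -0.08, -0.23 and -0.36, and in NMN mice 1 to 4 Lcn2 stood at 2.76, 3.62, 3.19 and 1.48. Its lipogenic genes Thrsp (-2.93), Elovl6 (-2.10) and Acly (-1.96) stood low on chip A, as did Fdps of cholesterol synthesis (-3.59). The mean of its cholesterol synthesis list was -2.10, against -0.82, -0.93 and -1.32 in the other HFD mice, and that of its lipid droplet list 1.37.

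NMN mouse 3 carried the highest lymphocyte and antigen presentation values of its group. The T cell genes Cd3d (1.26), Cd3g (0.95) and Ccl5 (1.37), and the MHC class II genes Cd74 (2.35) and H2-Aa (2.62) stood above the chow mean, together with the lipogenic gene Elovl6 (2.47). The mean of its B cell list was 2.32. Of the lists with too few members for a test, T and NK cell genes had a median change of -0.28 with the diet and 0.48 with NMN, cholangiocyte genes 0.09 and 0.48, erythroid genes 0.55 and -0.03, adipocyte genes 0.02 and -0.10, and acinar pancreas genes -0.41 and -0.03. In the limma test of the diet, Slc4a1, the anion exchanger of red cells, rose (1.88, SE 0.53, adjusted p = 0.0450).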
